A study of Mus musculus with 15 samples.

How the data were processed

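Messenger RNA from the brains of Kunming mice was measured in 15 libraries, 3 in each of 5 groups. The brain region and hemisphere sampled are not given in the sources used here. Per the labels' protocols, the RNA was extracted with a mirVana kit and the libraries were made with a TruSeq Stranded mRNA kit. Groups and replicate numbers were taken from the sample labels. The labels do not state that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

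The deposited table holds a whole-number read count per gene and library, per the file headers, and these counts were not normalized. It also holds FPKM values (fragments normalized by transcript length and sequencing depth), computed by the authors per the file headers. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and DESeq and the mouse genome build GRCm38 (mm10), without versions or roles. The counting tool, its strand setting and the annotation are not given in the sources used here. Reads from genes that overlap on opposite strands, and from near-identical copies such as the globin genes, could therefore have been assigned to either gene, and values for such genes are uncertain. 1 count column carried a name that matched the labels of no sample, and it was not used. Every line of the table named a gene.

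The table lists 18931 genes. Total counts ran from 18346180 to 20447465 per library, and 3 counts, taken as the floor of detection, correspond to 0.147 to 0.1635 CPM (counts scaled to a fixed library total). This floor covers counting error only. Gene coordinates, exon overlaps and transcript GC content come from the GENCODE mouse annotation of GRCm38. It matched 18524 genes (97.8%), by Entrez identifier or, failing that, by symbol. Levels are CPM scaled by TMM factors, which ran from 0.975 to 1.03, and are given as mean ± SD with n = 3.

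Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 15125. All 15 libraries entered 1 fit with a term per group, TMM scaling and robust estimation. The biological coefficient of variation was 27.1%, with 10 residual degrees of freedom. Log2 CPM values used a prior count of 2, while log2 fold changes came from the edgeR fit at its own default. A standard error (SE) is the fold change divided by the square root of the F statistic. Where a median size over genes is given with an SE, that SE is the median of the single-gene SEs. Adjusted p-values are Benjamini-Hochberg values within each contrast, with a threshold of 0.05. The contrasts were vehicle against sham, each treated group against vehicle, the treated groups against each other, and the departure of JU from additivity, which is JU minus JA minus UA plus vehicle on the log2 scale.

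Of 47 gene lists holding 691 genes, 674 of the genes were found in the table and 17 were not. 46 lists had at least 4 measured members and were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation. Adjusted p-values for lists are over the lists tested in a contrast. 17 genes belong to 2 or more lists. List scores per library are the mean log2 CPM of the members minus the sham mean. An injury score was computed from the genes past the threshold between vehicle and sham. It was the mean log2 CPM of those higher in vehicle minus that of those lower, relative to the sham mean. The 119 higher genes together therefore weigh as much as the 641 lower. Injury scores of JA, UA and JU were compared with a two-sided exact permutation test, and with 3 against 3 libraries the smallest p it can give is 0.1.

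Genes named in the text follow a rule. In each contrast it takes genes past the threshold with a mean of at least 1 CPM, all libraries of 1 group above all of the other, and a symbol that is not a predicted gene. Of these it names the 10 with the largest fold change up and the 10 down, without the condition on non-overlap for the departure from additivity. From each list reported it adds up to 4 members with the smallest p, and where fewer than 10 genes pass it takes the 10 genes with the smallest p. Genes chosen after their values were seen are named as such. Not every gene that the rule takes is reported here. The groups, contrasts, tests, lists, this rule and the alternatives were fixed before the data were examined, except those alternatives said below to be added.

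The procedure was tested on simulated counts for vehicle against sham with 200 genes changed. Among 15048 genes, 52.0% of genes changed 2-fold and 83.0% of those changed 4-fold were recovered, with 7 false calls among 142. With a trend on GC content added to the vehicle and JU libraries, 26 of 170 calls were false among 15026 genes, and 2 of 143 among 14913 genes when the trend was corrected. In a simulation with 1 raised list, camera called that list and 0 of the other lists. Its genes were drawn independently of each other, so it does not test the preset correlation between genes.

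The alternatives fixed in advance were the median-of-ratios size factors of DESeq2, no filter on low counts, the replicate number as a term, the Wald test of DESeq2 1.42.0, voom with quality weights, limma with a trend on log2(FPKM + 1), a fit of only the groups compared, an estimated correlation for lists, and each library left out in turn. After the data had been seen, the shared fit was repeated without JU replicate 1. A correction for transcript GC content was also added, alone, without JU replicate 1, and with only the groups compared. It removed a robust spline with 5 degrees of freedom per library, using the 15010 tested genes (99.2%) with a known GC content. The treated groups were compared with sham as an added contrast. The median return toward sham was computed again with each library left out, and the returned genes were counted again with the replicate number as a block. The injury score was also computed from the genes higher in vehicle alone. Tables were joined with Python 3.11.15. Mitochondrially encoded genes formed the list that was not tested, as fewer than 4 of its members were measured here.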

Results

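Brain messenger RNA was sequenced from Kunming mice, an outbred stock, in a model in which the middle cerebral artery is blocked (MCAO). The 15 libraries fell into 5 groups of 3, namely sham operation, occlusion with vehicle, and occlusion with the treatments labelled JA, UA and JU. The study title names jasminoidin combined with ursodeoxycholic acid, a bile acid, and asks about synergy against injury after ischemia and reperfusion. The labels do not spell out the abbreviations of the treatments. JU is compared below with JA and UA as if it were their combination, which the labels do not state. Total counts were 18346180 to 20447465 per library, with 16498 to 17052 genes detected in each. The 10 most abundant genes took 2.79% to 7.57% of the counts, with the highest share in JU replicate 1.

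Replicates of sham lay close together, while those of the other groups spread widely along the axis that separated sham from vehicle. The first principal component held 66.5% of the variance. Sham libraries lay between -40.4 and -39.1 on it and vehicle libraries between 27.1 and 84.2. JU replicate 1 lay at 129, beyond every vehicle library, while JU replicates 2 and 3 lay at -33.7 and -0.521. JA replicate 1 lay at 25.3, near the lower vehicle libraries, and the other JA libraries at -30.4 and -43.2. Spp1 (osteopontin, a secreted protein made by activated microglia and macrophages), chosen after its values were seen, shows this spread. Its level was 11.1 to 22.9 CPM in sham, 994.5 to 3077 in vehicle and 11.4 to 119 in UA. In JA replicate 1 Spp1 stood at 1410 CPM and in JU replicate 1 at 9707, against 24.1 and 31.7 in the other JA libraries and 9.23 and 46.2 in the other JU libraries. Replicate pairs of every group differed by more than sampling noise, with a chi-square per degree of freedom of at least 5.16.

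**Figure D1:**
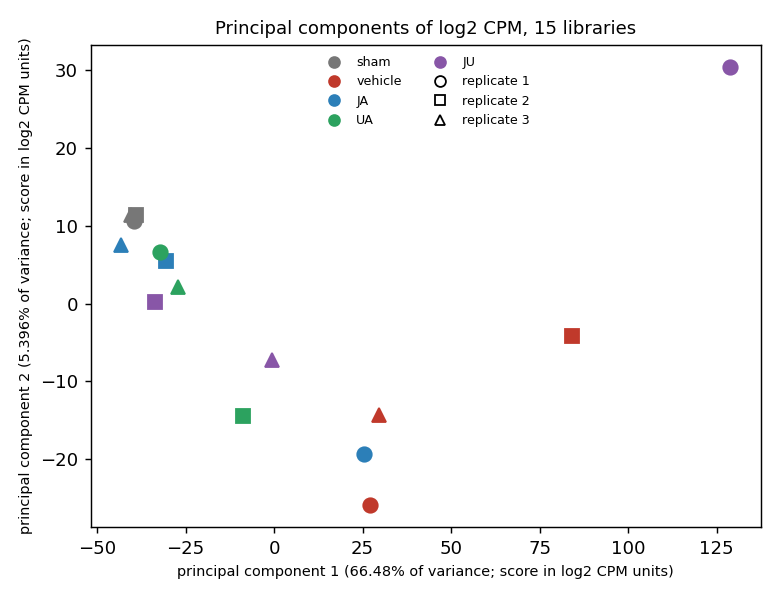
Each point is 1 library, placed by its scores on principal components 1 and 2 of log2 CPM, coloured by group, with 66.5% and 5.40% of the variance on the axes. The sham libraries sit together near -40, and JU replicate 1 stands alone at 129 on component 1.

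Genes of low GC content were lower in the vehicle and JU libraries than in the others. In the decile of genes with the lowest GC content, the median deviation from the mean of all libraries was -0.190 to -0.102 on the log2 scale in the 6 vehicle and JU libraries. In the 9 sham, JA and UA libraries it was 0.0327 to 0.165. JA replicate 1, with a reactive microglia score of 3.43 that lies within the vehicle range, stood at 0.0943.

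**Figure D2:**
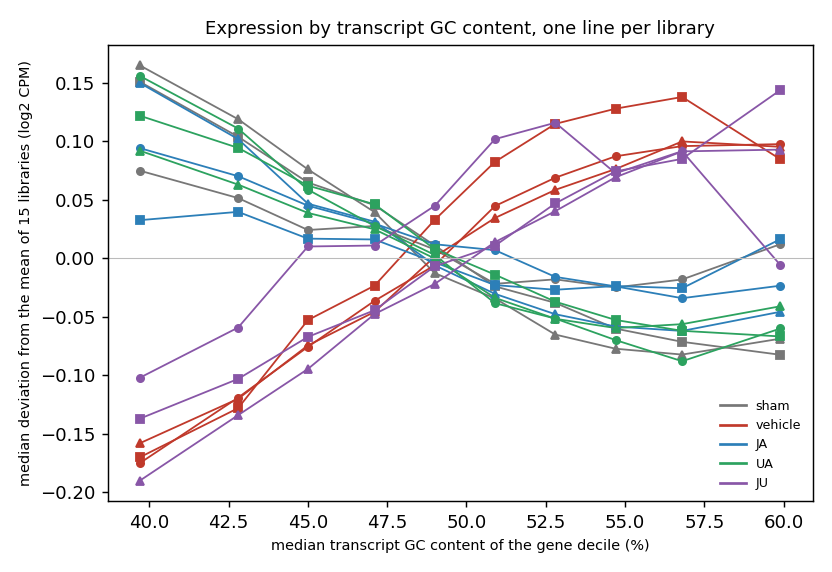
Each line is 1 library, coloured by group, and each point the median deviation (log2) of the tested genes in a decile of transcript GC content from the mean of all libraries. At the lowest GC content all 6 vehicle and JU libraries lie between -0.190 and -0.102 and the other 9 between 0.0327 and 0.165.

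The comparison of vehicle with sham asks what occlusion did to the brain transcriptome. Microglial genes were higher after occlusion and nuclear-encoded genes of oxidative phosphorylation were lower, each as a list, at a preset correlation between genes. These list calls were lost with an estimated correlation (smallest adjusted p = 0.601). Fcrls, a receptor typical of microglia (Entrez 80891; chromosome 3, 87250758 to 87263738, GRCm38), rose from 26.7 ± 4.38 to 304.3 ± 146 CPM (n = 3; log2 fold change 3.51 ± 0.71 SE, adjusted p = 0.0193). Ccl3, a chemokine (Entrez 20302; chromosome 11, 83647844 to 83649355), reached 24.1 ± 17.2 CPM in vehicle from a sham mean of 0.105 CPM, which is below the floor of detection (adjusted p = 0.0451). Cx3cr1, the microglial fractalkine receptor, rose by 2.02 ± 0.46 on the log2 scale (adjusted p = 0.0289). Tfrc, the transferrin receptor (Entrez 22042; chromosome 16, 32608920 to 32632794), fell from 144.5 ± 5.01 to 66.6 ± 8.72 CPM (log2 fold change -1.12 ± 0.16, adjusted p = 0.00796).

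All 28 measured genes of reactive microglia and macrophages had positive fold changes, with a median of 4.13. 0 passed the edgeR threshold over all genes and 25 passed when adjusted over the list alone, and the list rose as a set (camera adjusted p = 6.63e-14). No list kept its call in this contrast with an estimated correlation, at which the smallest adjusted p = 0.601. Trem2, a microglial lipid receptor, stood at 9.33 ± 0.868 CPM in sham and 149.5 ± 76.1 in vehicle (adjusted p = 0.0534). The 12 homeostatic microglia markers rose as a set with a median of 1.54 (adjusted p = 2.12e-11). Of these, 6 rose over all genes and 12 when adjusted over the list alone, among them Fcrls, Cx3cr1 and the transcription factor Sall1 at 1.11. Complement genes had a median of 3.24 (13 of 13 positive, adjusted p = 3.09e-06), 0 passing over all genes and 8 adjusted over the list alone. Reactive astrocyte genes had a median of 1.85 (20 of 20 positive, adjusted p = 3.36e-06), 0 over all genes and 2 adjusted over the list alone. Gfap, the astrocyte intermediate filament, stood at 191 ± 25.4 CPM in sham and 1684 ± 796 in vehicle (adjusted p = 0.0552). Cell cycle genes had a median of 2.28 (16 of 16 positive, adjusted p = 3.74e-07), with 0 and 13 passing by the same counts. Extracellular matrix genes had a median of 2.29 (20 of 20 positive, adjusted p = 5.53e-07), with 0 and 8.

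Genes of cholesterol synthesis fell as a set after occlusion, with negative values for 19 of 19 and a median of -0.86 (adjusted p = 1.7e-07, and adjusted p = 0.601 with an estimated correlation). 0 passed over all genes and 10 fell when adjusted over the list alone. Idi1, an isomerase of the isoprenoid pathway, stood at 20.04 ± 3.06 CPM in sham and 7.12 ± 2.47 in vehicle (adjusted p = 0.0902). Nuclear-encoded genes of oxidative phosphorylation fell with a median of -0.27 (19 of 20 negative, adjusted p = 3.36e-06), 3 over all genes and 12 adjusted over the list alone, and adjusted p = 0.601 with an estimated correlation. Pan-neuronal markers moved with them, with a median of -0.32 (14 of 14 negative, adjusted p = 0.00874, and 0.677 with an estimated correlation) and 0 passing by either count. The oxidative phosphorylation genes included Cox5a, a subunit of cytochrome c oxidase, at -0.70 ± 0.12 (adjusted p = 0.0128) and Ndufs1, a subunit of complex I, at -0.53 ± 0.10 (adjusted p = 0.0163). Hspd1, the mitochondrial chaperonin, fell by 0.45 ± 0.08 (adjusted p = 0.0112), and 3 heat shock genes fell over all genes and 6 adjusted over the list alone (list median -0.24, mean -0.02, adjusted p = 0.0464, and 0.601 with an estimated correlation). Without JU replicate 1 in the fit the heat shock list did not pass (adjusted p = 0.0881), and the list of the unfolded protein response did not pass, with a median of 0.17 (adjusted p = 0.179). Markers of striatal projection neurons had a median of -0.97 (16 of 16 negative, adjusted p = 2.1e-05, and 0.606 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone.

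Of 15125 genes tested with edgeR, 119 were higher and 641 lower in vehicle than sham. Genes lower in vehicle had a median transcript GC content of 41.9% and those higher 56.6%. With a correction for GC content 0 genes passed and 3075 had an unadjusted p under 0.05. The median absolute fold change of the called genes was 0.29 ± 0.11 (median SE) against 0.47 ± 0.10 before. The count was 2449 with DESeq2 (1066 higher and 1383 lower), 5363 with voom (2674 and 2689) and 3763 when only the 6 libraries compared were fitted (2030 and 1733). Leaving out sham replicates 1, 2 and 3 gave 365, 153 and 0 genes, leaving out vehicle replicates 1, 2 and 3 gave 292, 83 and 316, and leaving JU replicate 1 out of the shared fit gave 5172 (2589 and 2583). With both the GC correction and JU replicate 1 left out, 4196 genes passed, 509 of them among the 760. Of the lists, 17 rose and 10 fell among 46.

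**Figure D3:**
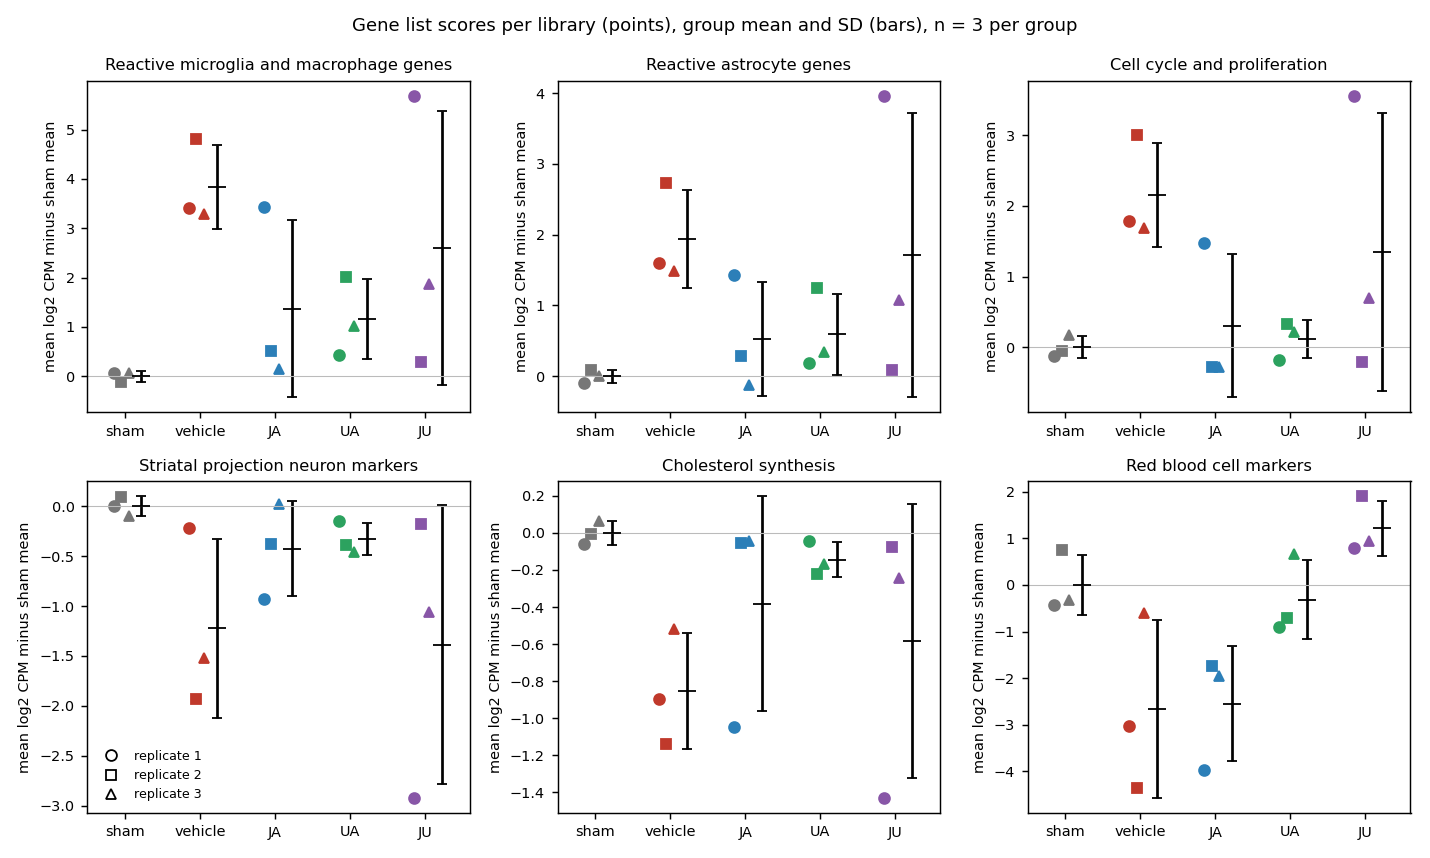
Each point is 1 library and each bar a group mean ± SD (n = 3) of the list score, the mean log2 CPM of the list's genes minus the sham mean, for 6 gene lists. For reactive microglia genes the vehicle libraries lie at 3.29 to 4.81 and JU replicate 1 at 5.68, while the other JU libraries lie at 0.278 and 1.86.

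The comparison of JA with vehicle asks what that treatment changed after occlusion. Tfrc rose from 66.6 ± 8.72 to 115 ± 18.2 CPM (n = 3; log2 fold change 0.79 ± 0.16, adjusted p = 0.0392). Kdm7a, a histone demethylase (Entrez 338523; chromosome 6, 39136623 to 39206789), rose from 39.1 ± 5.44 to 66.5 ± 5.81 CPM (0.77 ± 0.10, adjusted p = 0.0203). Slco1a4, an organic anion transporter of the blood-brain barrier that also carries bile acids, rose by 0.65 ± 0.14 (adjusted p = 0.0411), and Hspd1 by 0.35 (adjusted p = 0.0458). Genes that fell included Baiap2l2 at -1.83 ± 0.41 (adjusted p = 0.0478) and Igfbpl1 at -1.23 ± 0.28 (adjusted p = 0.0494).

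Homeostatic microglia markers fell as a set with JA, with a median of -1.16 (12 of 12 negative, adjusted p = 4.28e-09), 0 over all genes and 9 adjusted over the list alone. With an estimated correlation no list passed for JA against vehicle (smallest adjusted p = 0.705). Reactive microglia genes had a median of -1.93 (27 of 28 negative, adjusted p = 5.35e-09) with 0 passing by either count. Trem2 had a fold change of -2.37 and C1qb, a complement subunit, of -2.27, neither past the threshold. Cell cycle genes had a median of -1.77 (adjusted p = 4.15e-07) and cytoplasmic ribosomal protein genes of -0.36 (adjusted p = 1.25e-07), with all members negative and 0 passing by either count. Ependymal cell markers fell with a median of -1.10 (10 of 10 negative, adjusted p = 1.37e-06), 0 over all genes and 8 adjusted over the list alone. Cholesterol synthesis genes rose as a set by a median of 0.50 (19 of 19 positive, adjusted p = 0.000557) and striatal markers by 0.60 (16 of 16, adjusted p = 0.00228), with 0 passing by either count. The reactive microglia score of JA replicate 1 was 3.43, within the range of the vehicle libraries, and those of JA replicates 2 and 3 were 0.516 and 0.150.

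With JA, 225 genes were higher and 11 lower than with vehicle in edgeR. Genes higher with JA had a median GC content of 41.0% and those lower 56.2%. With the GC correction 0 passed and 1548 had an unadjusted p under 0.05. The median absolute fold change fell from 0.42 ± 0.08 (median SE) to 0.25 ± 0.09. DESeq2 called 937 genes (767 higher and 170 lower), voom 3549 (1820 and 1729), limma on FPKM 70, and edgeR with no filter on low counts 96. A fit of only the 6 libraries called 0, and so did a fit with the replicate number as a block. Leaving out vehicle replicates 1, 2 and 3 gave 0, 0 and 1 genes, leaving out JA replicates 1, 2 and 3 gave 23, 0 and 0, and leaving out JU replicate 1 gave 2899 (1716 and 1183), so the balance of higher and lower genes depended on the fit. With both the GC correction and JU replicate 1 left out, 1 gene passed and 4971 had an unadjusted p under 0.05. Of the 2891 genes called without JU replicate 1 that have a known GC content, 2882 kept their sign. The median absolute fold change of the 2891 went from 0.44 ± 0.11 (median SE) to 0.32 ± 0.11. Among 46 lists, 9 rose and 17 fell.

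The comparison of UA with vehicle asks the same of the other treatment. Genes of oxidative phosphorylation were higher with UA as a list (adjusted p = 0.673 with an estimated correlation), and Fcrls was lower. Fcrls fell from 304.3 ± 146 to 35.2 ± 6.20 CPM (n = 3; log2 fold change -3.11 ± 0.70, adjusted p = 0.0339). Tfrc rose from 66.6 ± 8.72 to 120.2 ± 3.72 CPM (0.85 ± 0.16, adjusted p = 0.0217). Cox5a rose by 0.64 ± 0.12 (adjusted p = 0.0219) and Chordc1, a partner of the chaperone HSP90, by 0.79 ± 0.16 (adjusted p = 0.0238). Evc2, a protein of the primary cilium (Entrez 68525; chromosome 5, 37338499 to 37425055), fell from 18.1 ± 5.97 to 7.60 ± 1.10 CPM (-1.25 ± 0.25, adjusted p = 0.0231).

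Oxidative phosphorylation genes rose as a set with UA by a median of 0.23 (20 of 20 positive, adjusted p = 2.25e-05), 2 over all genes and 5 adjusted over the list alone. For UA against vehicle no list passed with an estimated correlation (smallest adjusted p = 0.673). Pan-neuronal markers moved the same way, with a median of 0.32 (14 of 14 positive, adjusted p = 0.0109) and 0 passing by either count. Cholesterol synthesis genes rose by a median of 0.71 (19 of 19 positive, adjusted p = 2.36e-06), with 0 passing by either count, and Idi1 stood at 19.2 ± 5.08 CPM (adjusted p = 0.133). Heat shock genes rose by a median of 0.31 (10 of 14 positive, adjusted p = 0.00675), 3 over all genes and 4 adjusted over the list alone, while the unfolded protein list did not pass, with a median of -0.10 (adjusted p = 0.448). Reactive microglia genes had a median of -2.42 (28 of 28 negative, adjusted p = 4.74e-09), with 0 passing by either count. Homeostatic microglia markers fell by a median of -1.11 (12 of 12 negative, adjusted p = 1.47e-07), with Fcrls over all genes and 9 adjusted over the list alone. Cell cycle genes fell by a median of -2.14 (16 of 16 negative, adjusted p = 1.29e-07), 0 over all genes and 13 adjusted over the list alone. The list of bile acid receptors, transport and metabolism did not pass, with a median of -0.36 (adjusted p = 0.409), 0 over all genes and 1 member raised when adjusted over the list alone. It passed in none of the 8 contrasts.

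With UA, 472 genes were higher and 53 lower than with vehicle in edgeR. Median GC contents were 41.6% for genes higher with UA and 57.3% for those lower. With the GC correction 0 passed and 2018 had an unadjusted p under 0.05. The median absolute fold change fell from 0.44 ± 0.09 (median SE) to 0.24 ± 0.10. DESeq2 called 1516 genes (1105 higher and 411 lower), voom 4113 (2162 and 1951), and a fit of only the 6 libraries 2159 (1148 and 1011). Leaving out vehicle replicates 1, 2 and 3 gave 37, 0 and 220 genes, leaving out UA replicates 1, 2 and 3 gave 19, 76 and 89, and leaving out JU replicate 1 gave 4300 (2255 and 2045). With both the GC correction and JU replicate 1 left out, 2007 passed, 242 of them among the 525. With the GC correction and only the groups compared, 1 gene passed. As sets, 11 of the 46 lists rose and 17 fell.

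Of the genes higher than vehicle, 201 were shared by JA and UA, against 7.02 for independent lists and a mean of 0 in 20 simulations of unchanged groups against the same vehicle libraries. Of those lower, 4 were shared, against 0.0385 and 0. The value for independent lists leaves out the shared vehicle libraries and the simulations leave out the effects, so neither gives the overlap to be had without a shared effect. The fold changes of JA and UA against vehicle had a covariance of 0.305 across genes (r = 0.908), against 0.0737 in the simulations (r = 0.502). Part of the excess may come from the shared controls, since 3 vehicle libraries are too few to divide, and genes are not independent replicates. Genes higher with JA and with UA were both of low GC content (medians of 41.0% and 41.6%), and the simulations held no such trend. With the GC correction 0 genes passed in either contrast, so the overlap of calls cannot be told apart from that trend. The covariance was then 0.282 (r = 0.905).

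The comparison of JU with vehicle asks what the third treatment changed. 0 genes passed with edgeR, 300 had an unadjusted p under 0.05, and every adjusted p was 1.0. DESeq2 also called 0 genes and voom 20. Fcrls stood at 180.8 ± 163 CPM and Tfrc at 79.6 ± 19.8 (n = 3), between the vehicle and sham means. Slc25a37, the mitochondrial iron importer mitoferrin, had a fold change of 0.45 ± 0.09 and Zfp366, a zinc finger protein, of 0.78 ± 0.17, with non-overlapping libraries.

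Red blood cell markers rose as a set in JU, with a median of 3.10 (6 of 6 positive, adjusted p = 6.5e-23, and adjusted p = 0.0114 with an estimated correlation). 0 passed over all genes and 6 when adjusted over the list alone. Hba-a1, an alpha globin gene whose reads may be shared with its near-identical copy, stood at 130.3 ± 11.9 CPM in JU. Its level was 16.2 ± 22.2 in vehicle, 51.7 ± 13.1 in sham, 11.3 ± 8.27 in JA and 65.5 ± 43.5 in UA. Cholesterol synthesis genes rose as a set by a median of 0.34 (19 of 19 positive, adjusted p = 1.24e-05, and adjusted p = 0.775 with an estimated correlation), with 0 passing by either count. Hippocampal neuron markers fell by a median of -0.36 (9 of 11 negative, adjusted p = 1.36e-05, and 0.246 with an estimated correlation). For reactive microglia genes the median was 0.25 and the mean 0.24, while the set test pointed down (adjusted p = 0.00168). With an estimated correlation only 1 list passed in this contrast, that of the red blood cell markers. The red blood cell score was lowest in JU replicate 1 among the JU libraries, at 0.795 against 1.90 and 0.950. JU replicate 1 decided the values of the other lists named here. Without it the median of reactive microglia genes was -2.13 (adjusted p = 1.6e-12 at the preset correlation). That of cell cycle genes was -2.10 instead of 0.0035, and that of cholesterol synthesis genes 0.69. The hippocampal markers did not pass (adjusted p = 0.293). Of the 46 lists, 10 rose and 7 fell, and 27 lists passed without JU replicate 1.

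The comparison of JU with JA asks whether the third treatment differed from the former. 0 genes passed with edgeR and 3074 had an unadjusted p under 0.05. DESeq2 called 608 genes (193 higher and 415 lower) and voom 2000 (498 and 1502). Nr1d2, a nuclear receptor of the circadian clock, stood at 90.6 ± 10.1 CPM in JU and 133 ± 7.55 in JA (n = 3; log2 fold change -0.56 ± 0.08, adjusted p = 0.0812). Gfap stood at 2280 ± 2232 CPM in JU and 428.7 ± 346 in JA (adjusted p = 0.189). Red blood cell markers were higher in JU by a median of 3.57 (6 of 6, adjusted p = 4.68e-06, and 0.596 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone. Reactive astrocyte genes were higher by a median of 2.12 (20 of 20, adjusted p = 9.09e-06, and 0.596 with an estimated correlation) with 0 passing by either count, and without JU replicate 1 their median was 0.10 and the list did not pass (adjusted p = 0.773). Of the 46 lists, 24 were higher and 7 lower, and without JU replicate 1 6 lists passed. With an estimated correlation the smallest adjusted p = 0.596.

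The comparison of JU with UA asks the same against the latter. Evc2 was higher in JU, at 19.8 ± 4.06 CPM against 7.60 ± 1.10 in UA (n = 3; log2 fold change 1.38 ± 0.25, adjusted p = 0.0436). Celsr1, a cadherin of planar cell polarity, was higher by 0.92 ± 0.19 (adjusted p = 0.0449) and Pdgfb, a growth factor for pericytes, by 0.67 ± 0.14 (adjusted p = 0.0485). Ndufb1, a subunit of complex I (Entrez 102631912, with no match in the annotation), was lower at 24.6 ± 3.28 CPM against 42.4 ± 4.45 (-0.78 ± 0.13, adjusted p = 0.0436). Oxidative phosphorylation genes were lower as a set by a median of -0.22 (20 of 20, adjusted p = 0.000133, and 0.531 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone. Cell cycle genes were higher by a median of 2.17 (16 of 16, adjusted p = 0.000208, and 0.531 with an estimated correlation), 0 over all genes and 15 adjusted over the list alone. Extracellular matrix genes were higher by 2.37 (19 of 20, adjusted p = 0.000133, and 0.531 with an estimated correlation), with 0 and 12 by the same counts. Without JU replicate 1 the medians of these 3 lists were -0.12, 0.19 and 0.08 in the same order, and none passed (adjusted p = 0.0639, 0.605 and 0.605). The pan-neuronal score moved the way of oxidative phosphorylation, with JU minus UA at -0.408 and overlapping libraries. It stood at -1.25 in JU replicate 1 against 0.0324 and -0.123 in the other JU libraries.

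Between JU and UA 15 genes were higher and 149 lower with edgeR, with median GC contents of 58.2% and 41.3%. With the GC correction 0 passed and 2467 had an unadjusted p under 0.05. The median absolute fold change fell from 0.45 ± 0.08 (median SE) to 0.25 ± 0.09. DESeq2 called 1565 genes (732 higher and 833 lower), voom 2985 (966 and 2019) and limma on FPKM 277. With other size factors, no filter on low counts, the replicate number as a block or only the 6 libraries fitted, edgeR called 0. It called 0 without UA replicate 1, 2 or 3 or JU replicate 3, 95 without JU replicate 1 (3 higher and 92 lower), and 3068 without JU replicate 2, where most were higher (1797 and 1271). Of the 46 lists, 20 were higher and 10 lower, and 0 passed without JU replicate 1. With an estimated correlation the smallest adjusted p = 0.531.

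Between JA and UA 0 genes passed with edgeR, with 328 genes at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom. Evc2 stood at 18.2 ± 2.64 CPM in JA and 7.60 ± 1.10 in UA (n = 3; log2 fold change 1.26 ± 0.25). Red blood cell markers were lower in JA by a median of -2.36 (6 of 6, adjusted p = 1.8e-11, and 0.187 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone. Oxidative phosphorylation genes were lower by a median of -0.12 (19 of 20, adjusted p = 2.45e-06, and 0.949 with an estimated correlation), with 0 by either count. Of the 46 lists, 2 were higher in JA and 6 lower. The count of lists was 15 without JA replicate 2, 14 without JA replicate 3 and 13 without UA replicate 3.

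The departure of JU from additivity asks whether JU differed from the sum of the JA and UA changes, which bears on synergy if JU is their combination. As lists, reactive microglia and cell cycle genes were higher in JU than that sum, which itself lay below sham for both. Oxidative phosphorylation genes were lower than the sum as a list. These are the directions in which vehicle differed from sham. These list calls too were lost with an estimated correlation (adjusted p = 0.592 for each), and the median of reactive microglia genes went from 4.53 to 1.76 without JU replicate 1. Fcrls departed by 4.63 ± 0.96 on the log2 scale (n = 3 per group, adjusted p = 0.0102). Ak7, an adenylate kinase of motile cilia, departed by 1.95 ± 0.42 (adjusted p = 0.0126). Hspd1 departed by -0.64 ± 0.11 (adjusted p = 0.00449), with 132 ± 8.33 CPM in vehicle, 169 ± 4.48 in JA, 169.9 ± 2.61 in UA and 139.5 ± 7.63 in JU. Akr1e1, an aldo-keto reductase, departed by -1.65 ± 0.29 (adjusted p = 0.00475). Fabp4, a fatty acid-binding protein, stood at 8.14 ± 13.8 CPM in JU, with 24.1 CPM in JU replicate 1.

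Reactive microglia genes departed upward by a median of 4.53 (28 of 28 positive, adjusted p = 3.09e-07), 14 over all genes and 23 adjusted over the list alone. The smallest adjusted p of any list for the departure was 0.592 with an estimated correlation. Without JU replicate 1 the reactive microglia list still passed (adjusted p = 0.000196), with 0 genes passing over all genes. Cell cycle genes departed by a median of 3.96 (adjusted p = 4e-06), 13 over all genes and 16 adjusted over the list alone, and by 1.85 without JU replicate 1 (adjusted p = 0.000105), with 1 over all genes. Ribosomal protein genes departed by 0.58 (22 of 22 positive, adjusted p = 1e-04), with 8 and 10 by the same counts, and by 0.34 without JU replicate 1 (adjusted p = 0.0026). Oxidative phosphorylation genes departed by -0.33 (20 of 20 negative, adjusted p = 0.000521), 5 over all genes and 7 adjusted over the list alone, and by -0.25 without JU replicate 1 (adjusted p = 0.00905). JU replicate 1 had the highest reactive microglia score of all libraries, at 5.68. JU replicates 2 and 3 scored 0.278 and 1.86 for these genes, against means of 1.37 in JA, 1.16 in UA and 3.83 in vehicle. For cell cycle genes they scored -0.214 and 0.691, against 0.307, 0.118 and 2.15. In both lists the sum of the JA and UA changes lay below sham. The departures left without JU replicate 1 therefore do not show that the other JU libraries lay above JA or UA. In all, 1470 genes departed upward and 1671 downward, with median GC contents of 54.7% and 42.6%. With the GC correction 0 passed and 4433 had an unadjusted p under 0.05. The median absolute departure fell from 0.83 ± 0.20 (median SE) to 0.53 ± 0.21.

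For the departure DESeq2 called 4755 genes (2603 upward and 2152 downward) and voom 5609 (2584 and 3025), and a fit of only the 4 groups called 1057 (198 and 859). The lowest counts without 1 library were 974, 1004, 1241, 1270, 1273, 1321 and 1892, without JA replicate 3, vehicle replicate 2, UA replicate 3, JA replicate 2, UA replicate 2, UA replicate 1 and vehicle replicate 3. Without JU replicate 2 the count was 5539 and without JU replicate 1 it was 2979 (937 upward and 2042 downward), of which 2422 were among the 3141. As sets, 18 of 46 lists departed upward and 11 downward.

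A last comparison asks how far each treatment returned the genes changed by occlusion toward sham. Of the 760 genes, 205 passed the threshold in the opposite direction with JA, 445 with UA and 0 with JU, and the opposite sign was seen in 759, 759 and 596. The median fold change was 77.1% of the occlusion change with JA, 90.02% with UA and 13.6% with JU. The JU value rested on single libraries, at 25.8% without JU replicate 1, 1.92% without JU replicate 2 and 6.53% without vehicle replicate 2. Most of these genes, 641, were lower in vehicle than sham, with a median GC content of 41.9%. Genes of low GC content were lower in all vehicle and JU libraries, so the lower JU value cannot be told apart from that trend. The same vehicle libraries enter both sides of these comparisons. Across genes, vehicle minus sham had a covariance of -0.373 with JA minus vehicle, -0.409 with UA minus vehicle and -0.123 with JU minus vehicle, against -0.0728, -0.0733 and -0.073 in simulations of unchanged groups. Without JU replicate 1 in the shared fit, more genes were changed by occlusion, and 2527 of them passed in the opposite direction with JA, 3713 with UA and 1 with JU. With the GC correction no genes were left to count, while the covariances were -0.349 with JA minus vehicle, -0.382 with UA minus vehicle and -0.121 with JU minus vehicle.

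The injury score over the 760 genes was 1.56 ± 0.236 in vehicle (n = 3) against 0.0682 SD around 0 in sham. It was 0.468 ± 0.263 with JA, 0.353 ± 0.125 with UA and 1.24 ± 0.534 with JU. JU lay above UA by 0.889 (exact permutation p = 0.1, the smallest possible with 3 against 3) and above JA by 0.773 (exact permutation p = 0.2). With only the score genes higher in vehicle, JU lay above UA by 0.518 and above JA by 0.463 (exact permutation p = 0.1 and 0.2). The differences were 1.1 and 0.962 with the GC correction and genes taken from the 14 libraries (exact permutation p = 0.3 and 0.6). JA and UA differed by 0.116 (exact permutation p = 0.7). With the genes of the score chosen again each time 1 library was left out, that difference turned to -0.285 without JA replicate 1, and was 0.182, 0.254 and 0.228 without JA replicate 2, JA replicate 3 and UA replicate 2. JU libraries scored 1.81, 0.745 and 1.17. The injury score did not order the libraries as the reactive microglia genes did. JA replicate 1 and JU replicate 2 scored 0.75 and 0.745, with reactive microglia scores of 3.43 and 0.278. In the decile of lowest GC content they stood at 0.0943 and -0.137. A higher injury score in JU therefore cannot be read as more injury by itself. JU lay above JA by 0.206 without JU replicate 1, 1.67 without JU replicate 2 and 1.33 without JA replicate 1. It lay above UA by 0.338 and 1.78 without JU replicates 1 and 2. Against sham itself, edgeR called 0 genes for JA and 0 for UA, with 500 and 193 at an unadjusted p under 0.05, and 121 higher and 441 lower for JU, or 50 and 352 without JU replicate 1. For JU against sham the counts were 0 and 0 with the GC correction, with all libraries and without JU replicate 1, and 3662 and 1214 genes had an unadjusted p under 0.05. Without JU replicate 1, 11 lists were higher and 9 lower than sham for JA, 12 and 3 for UA, and 10 and 4 for JU, and none passed with an estimated correlation (smallest adjusted p = 0.324, 0.191 and 0.875). Reactive microglia genes were among those higher in both (adjusted p = 4.95e-10 for JA and 1.42e-11 for UA, or 0.662 and 0.722 with an estimated correlation), and thalamic neuron markers among those lower (adjusted p = 4.67e-11 and 1.44e-13, or 0.324 and 0.191). The thalamic score split the sham libraries, at 0.251 and 0.318 in replicates 1 and 2 but -0.569 in replicate 3, within the UA range of -0.634 to -0.511.

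**Figure D4:**
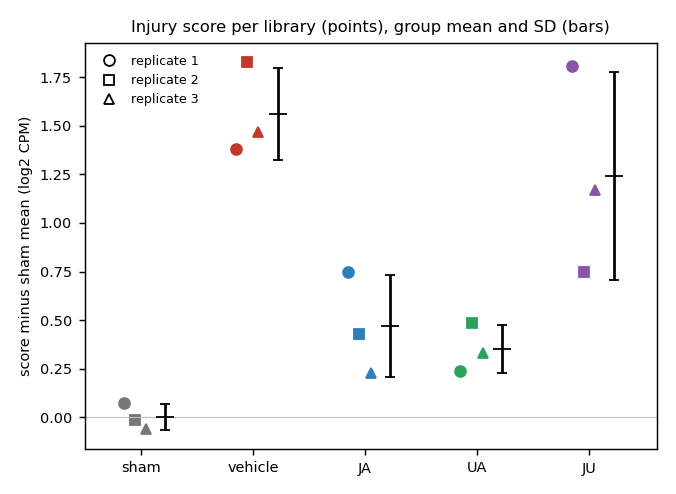
Each point is 1 library and each bar a group mean ± SD (n = 3) of the injury score, in log2 CPM relative to the sham mean, over the 760 genes changed between vehicle and sham. The JA and UA libraries lie between 0.229 and 0.75, and the JU libraries between 0.745 and 1.81.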

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

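The departure of JU from additivity was a planned test, and the tests of the other splits, of the additive sum and of GC content below were chosen only after its result was seen. In 3141 genes and 29 gene lists the effect of JA in the presence of UA, taken as JU minus UA, differed from its effect without UA, JA minus vehicle, by a test of the difference itself. With an estimated correlation 0 of the lists passed (smallest adjusted p = 0.592). The comparison holds only if JU is the combination of both, which the labels do not state.

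A sum of single effects that passes sham may account for part of this departure. In 3123 of the 3141 genes the additive sum lay beyond sham, against 11632 of all 15125. With JU replicate 1 included, the distance from sham to the sum was a median of 46.1% of the departure (quartiles 37.6% and 56.1%). This lies between the bounds of 25% and 50% set for the test, and the share without JU replicate 1 was not computed. GC content removed a median of 33.6% of the departure, also between those bounds, or 50.6% without JU replicate 1 (quartiles 29.6% and 68.4%), just over the upper bound. All these quartiles are over genes, and the uncertainty of the shares between libraries was not computed. With the correction the call ended in every gene. The median size fell from 0.83 ± 0.20 (median SE) to 0.53 ± 0.21, and without JU replicate 1 from 0.64 ± 0.14 to 0.32 ± 0.14. Why the calls ended was not tested. These explanations cannot be told apart from a treatment effect, because the shares lie between or near the bounds and the trend with GC content follows the groups. Of 100 drawn splits of the 12 libraries, 2 gave as many genes, the real one included, so chance can be excluded for the genes only in the sense that the 4 groups differ in some way. These splits mix the groups' other differences into the spread and do not test the departure by itself, and 1 split called 3934. For the lists 30 of 100 splits gave as many, the highest 35, so chance cannot be excluded.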

How the results depend on the processing

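The alternatives with GC correction, the treated groups against sham, the returned genes under any other setting, the injury score of genes higher in vehicle alone and the shared fit without JU replicate 1 were chosen only after the results were seen; all others were planned. Of 207 planned values of counts and scores, 130 were kept. A count was kept if its total was the same or within 1.5 times, and a score difference if its direction was the same. The rule for counts leaves out the balance of higher and lower genes, and 0 against 0 is kept. The departure without JU replicate 3 was kept with 2326 genes upward and 1781 downward, against 1470 and 1671. Of the values that moved, the cause was not tested.

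Size factors gave 0 genes for JU against UA. Without a filter on low counts, JA against vehicle gave 96 and JU against UA 0. The DESeq2 Wald test gave 2449 genes for vehicle against sham, 937 for JA and 1516 for UA against vehicle, 608 for JU against JA, 1565 for JU against UA, 1 for JA against UA and 4755 for the departure. Of the 2449, 1066 were higher in vehicle, against 119 of 760 in edgeR. In the same order voom gave 5363, 3549, 4113, 2000, 2985, 0 and 5609, and 20 for JU against vehicle. FPKM values gave 70 for JA against vehicle and 277 for JU against UA. A fit of only the groups compared gave 3763 for vehicle against sham, 0 for JA, 2159 for UA, 0 for JU against UA and 1057 for the departure.

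With the replicate number as a block the counts were 383 for vehicle against sham, 0 for JA, 191 for UA, 0 for JU against UA and 1974 for the departure, and 0 (JA) and 167 (UA) genes returned toward sham. The deviations from the group means gave no sign that the numbers pair the samples. Their mean correlation was -0.00786 for pairs with the same number and 0.0122 for the others. Of 30 pairs with the same number, 7 had a correlation over 0.1, and 6 of 15 libraries lay closest to their own number. With so few libraries a pairing is not excluded.

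The GC correction gave 0 genes for vehicle against sham, JA, UA, JU against UA and the departure, and 0 returned. Without JU replicate 1 as well it gave 4196, 1, 2007, 0 and 0, with 1 for JU against vehicle, and 1 (JA), 1781 (UA) and 1 (JU) returned. Lists were then 27 for JU against vehicle, 7 for JU against JA and 8 for JU against UA. With the groups compared alone the corrected counts were 2105, 0, 1, 0 and 0. An estimated correlation left 1 list for JU against vehicle and 0 in the other 7 contrasts.

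With 1 library left out, counts ran from 0 to 5172 for vehicle against sham (lowest without sham replicate 3), 0 to 2899 for JA, 0 to 4300 for UA (lowest without vehicle replicate 2), 0 to 1 for JU against vehicle, 0 to 0 for JU against JA and for JA against UA, 0 to 3068 for JU against UA, and 974 to 5539 for the departure. The highest were without JU replicate 1, or JU replicate 2 in the last 2 cases. The biological coefficient of variation of the shared fit was 27.1%, and 16.7% without JU replicate 1. Lists ran from 21 to 28, 20 to 30, 20 to 31, 15 to 27, 6 to 36, 0 to 31, 9 to 15 and 21 to 30 in the order of the report. Returned genes were 2527 (JA), 3713 (UA) and 1 (JU) without JU replicate 1. Injury score differences ran from -0.285 (reversed) to 0.254 for JA against UA, 0.206 to 1.67 for JU against JA and 0.338 to 1.78 for JU against UA.

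Of 206 values of genes taken by the rule for named genes, 30 fell short of the threshold with other size factors, 51 without the filter, 85 with the replicate block, 4 with voom and 6 with DESeq2, where 56 and 44 more passed. With FPKM 29 of 200 fell short, and 51 of 205 with only the groups compared. With the GC correction 115 of 202 fell short, and with 1 library left out 569 of 1502, and 0 turned direction in any of these settings. Ccl3 in sham lay below the floor of 3 counts, so depth limits its fold change.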

Other observations

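The tests in this part of other splits, of GC content and of JU replicate 1 were chosen only after the results were seen; the list tests were planned.

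Other groups of genes also moved with occlusion. Cytokines and chemokines had a median log2 fold change of 3.43 in vehicle against sham (14 of 15 positive, adjusted p = 1.56e-05), 1 over all genes and 7 adjusted over the list alone. Targets of NF-kB, a transcription factor of inflammation, had a median of 1.03 (14 of 14 positive, adjusted p = 1.98e-05), 0 over all genes and 6 adjusted over the list alone. Inflammasome genes had a median of 1.43 (9 of 10 positive, adjusted p = 0.00263), with 0 and 5. Ependymal markers had a median of 0.95 (10 of 10 positive, adjusted p = 0.000527), with 0 and 3. Genes of GABA receptors and ion channels had a median of -0.42 (18 of 18 negative, adjusted p = 0.00166), and Kcna1, a potassium channel, was the 1 member that fell by either count, at -0.46 (adjusted p = 0.0333). The adjusted p was 0.601 or above for each with an estimated correlation.

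Markers of some cell types and regions differed between libraries of 1 group. The red blood cell score was -3.03, -4.36 and -0.598 in vehicle and -3.97, -1.73 and -1.95 in JA, but 0.795, 1.90 and 0.950 in JU. Cerebellar markers scored 2.21 in UA replicate 2 and 1.36 in JA replicate 3. The choroid plexus score of vehicle replicate 1 was -2.60, and Ttr, a choroid plexus transcript chosen after its values were seen, stood at 9.26 CPM there against 1120 and 1018 in the other vehicle libraries. Immediate early genes scored 0.833 ± 0.139 in UA (n = 3) and 0.261 ± 0.550 in vehicle, and the list rose with UA by a median of 0.66 (15 of 19 positive, adjusted p = 0.0166), or 0.673 with an estimated correlation, with 0 members past the threshold over all genes and 0 adjusted over the list alone.

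Genes of low GC content were lower in all 6 vehicle and JU libraries. The 4 vehicle and JU libraries whose microglia score lay within the range of the other groups (up to 3.43) all lay below the lowest-decile range of those groups. That limit is JA replicate 1 alone, and the next highest score was 2.02 in UA replicate 2. Without JA replicate 1 only JU replicates 2 and 3 lie within the range, at -0.137 and -0.19 in the lowest decile, too few for the test. As that test was set, the argument against the level of injury as the whole source therefore rests on JA replicate 1. JU replicates 2 and 3 by themselves still lay below the range of the sham, JA and UA libraries (0.0327 to 0.165). GC content bias between libraries may be part of the JA difference. Without JU replicate 1 the trend removed a median of 27.4% of the JA minus vehicle fold change, between the bounds of 25% and 50%. The calls ended, 2891 becoming 1, and the median size fell from 0.44 ± 0.11 (median SE) to 0.32 ± 0.11. For UA against vehicle the trend removed a like share, 27.1%, and 1633 of 4284 genes stayed past the threshold. In this fit the loss of the JA calls therefore does not follow from the share removed alone. For vehicle against sham the trend removed 20.8%, and 3179 of 5151 stayed. With only the groups compared, the UA calls were lost too, 2159 becoming 1. Handling or library preparation shared by the vehicle and JU groups cannot be told apart from an effect of the groups, as 0 groups had libraries on both sides of 0 in the lowest decile.

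JU replicate 1 stood apart from the other JU libraries in the direction of occlusion. Its difference from their mean correlated with vehicle minus sham at r = 0.818 across 15125 genes, which are not independent replicates, with a slope of 1.35, and 1485 of 1516 genes over 2-fold in vehicle had the same sign. More severe injury in that library stays open, since the library was singled out on the component that separates sham from vehicle and the correlation restates that. The lowest vehicle score of reactive microglia genes, 3.29, was above both other JU libraries at 0.278 and 1.86, but by less than these differ, so a swap with a vehicle library stays open too. A single wrong label, or a swap with another group, was not tested.

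Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 split with as many genes for vehicle against sham (760, highest other 0), JA against vehicle (236, highest other 7), UA against vehicle (525, highest other 0) and JU against UA (164, highest other 0). For JU against vehicle, JU against JA and JA against UA the real count was 0, so all 10 splits gave as many, the highest other being 3262, 494 and 0. The split calling 3262 set JU replicate 1 with vehicle replicates 2 and 3 against the other 3 libraries, which points to a structure of these samples other than the groups, and so does the 494 of JU replicates 1 and 3 with JA replicate 1. For lists, the number of splits with as many and the highest other were 6 and 33 for vehicle against sham (27), 5 and 31 for JA (26), 4 and 31 for UA (28) and 9 and 32 for JU against vehicle (17). They were 2 and 31 for JU against JA (31), 5 and 35 for JU against UA (30) and 10 and 22 for JA against UA (8).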
